A study of Mus musculus with 18 samples.

How the data were processed

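Liver RNA of CD1 mice was measured on 18 Affymetrix mouse expression arrays, 3 in each of 6 groups. Per the labels, RNA was extracted with a Qiagen kit and biotin-labelled cRNA was made from 200 ng of it. The deposited values are on the log2 scale, made by the authors with Affymetrix Expression Console version 1.1 and RMA (background correction, quantile normalisation and summary of the probes of each probe set). The mean of the arrays was 5.09 for the prevention model and 5.25 for the reversal model, with array means from 5.08 to 5.10 and from 5.25 to 5.26, so the values fell at 2 levels, 1 for each model. Which arrays were run together is not stated. Arrays give no depth; the number of arrays limits the precision, and the labels do not state whether the 3 arrays of a group came from 3 animals, so each p measures spread between arrays.

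The table held 45101 probe sets, 64 of them control probe sets. The probe table paired 34945 probe sets with exactly 1 gene symbol, paired 932 with several symbols and did not list 9160. Of the probe sets with 1 symbol, 34741 had a gene ID that matched the mouse gene table, all with the same symbol. The 40% of probe sets with the lowest mean over all arrays were dropped, and each gene was represented by its probe set with the highest mean, chosen without regard to group. Of 18193 genes with at least 1 probe set, 13221 were tested. Of the tested probe sets, 1520 have names ending in _s_at or _x_at, which can cross-hybridise between related transcripts, such as those of the Cyp2, Ugt and Mup families.

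Replicates 2 and 3 of the CMPF group of the prevention model were nearly identical. Of the 13221 genes, 0 differed more than 2-fold between them, against at least 115 in each of the other 152 pairs of arrays and a median of 250 in pairs of 1 group. Over 3719 bright genes, the SD of their difference was 0.102, against at least 0.277 in the other pairs. The plan made before the data were examined counted all 18 arrays; these 2 were instead averaged and counted as 1 sample, so that this group has n = 2, and the count of all 18 is given as an alternative. The fit therefore had 17 samples.

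Groups were compared with limma 3.58.1 in R 4.3.3: 1 linear model of the 6 group means with 11 residual degrees of freedom, moderated by empirical Bayes (prior degrees of freedom 3.02). Adjusted p is Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The comparisons were HFD against chow, CMPF against vehicle on HFD, and CMPF on HFD against chow in each model, and the differences of the HFD effects and of the CMPF effects between models. A gene's effect is its log2 fold change with its standard error (SE). Of 42 gene lists written before the data were examined (pathways, stress responses, cell type markers and liver zonation), 40 were tested with limma's fry, with Benjamini-Hochberg adjustment over the 40 lists of a comparison. Of 749 list memberships, 611 had a tested gene; Cyp2c44 was matched as Cyp2c23 and Ctgf as Ccn2. The fry test asks whether the genes of a list move, on balance, in 1 direction; it compares a list with neither other genes nor other lists. Each list was also tested with limma's camera, with a preset correlation of 0.01 and with a correlation estimated for each list. Camera asks another question, whether a list moves more than the other genes do. List results given with a preset or an estimated correlation are from camera, so a call lost there was not lost to the correlation alone.

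The 100 genes with the highest and the 100 with the lowest moderated t for HFD in 1 model were used as sets for the CMPF effect in the other model, which shares no array with it. Correlations of effects between models are across genes, which are not independent replicates, and are set beside all 10 splits of the 6 reversal arrays. The named genes were chosen by a rule made before the data were examined. In each comparison of HFD with chow and of CMPF with vehicle, it took up to 10 genes per direction with the largest effect among those past the threshold whose groups did not overlap; groups of 3 against 3 do not overlap for 10% of genes by chance. Where fewer than 3 genes in a direction met this, it took the 3 with the smallest p, given as values. It took the 2 members with the smallest p of each list described (4 where the list passed) and 12 genes always given: Fgf21, Srebf1, Fasn, Acaca, Acacb, Scd1, Cpt1a, Ppara, Pparg, Cd36, Pck1 and G6pc. For differences between models it took 5 genes per direction. Predicted genes and clones were tested but not named. Members of lists named for CMPF on HFD against chow, and for differences of the HFD effect, were the 4 with the smallest p, chosen after their values were seen.

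RNA integrity was followed with the control probe sets: the 3' to 5' index is the mean over Gapdh and beta-actin of the 3' minus the 5' signal (log2), and it is higher where RNA is shorter. The pipeline was tested on simulated data, with 200 of 13221 genes shifted in 20 draws per comparison. Noise was drawn independently for each gene and array, with the real means and residual SDs of the genes. It held no correlation between genes and no difference in RNA integrity, so the rates below may not hold for the real arrays. A shift of 1 on the log2 scale was recovered for 75.1% of genes in HFD against chow in prevention, 67.8% in CMPF against vehicle in prevention, 74.5% in HFD against chow in reversal and 74.0% in CMPF against vehicle in reversal. The share of false calls was 4.89%, 6.09%, 5.46% and 5.30%, and the sign was right for 100% of recovered genes. A list shifted by 0.5 was called in 20, 17, 19 and 20 of the 20 draws, with 0, 1, 5 and 3 calls of other lists.

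The alternatives were: no filter on dim probe sets, or 60% dropped; the mean of a gene's probe sets; every probe set with no collapse to genes; quantile normalisation, subtraction of array medians or cyclic loess over all arrays; a trended, robust prior; array weights; fits on the arrays of 1 model or of the 2 groups compared; the replicate number as a block; camera in place of fry; sets of 50 or 200 genes; a threshold of 0.10; and each sample left out in turn. Chosen after seeing the data were: all 18 arrays counted separately; the index as a covariate; the reversal comparisons without the 2 reversal arrays of lowest index (HFD 1 and CMPF 3); and the prevention comparisons without the 2 prevention arrays of lowest index (chow 1 and 3). Leaving out prevention chow 1 and 3 leaves 1 chow array, so calls lost there may be lost to the fewer arrays alone. No array was left out of the results otherwise. The values of 1 gene are not reported here.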

Results

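Liver gene expression was measured in CD1 mice fed chow or a high-fat diet (HFD) with 60% of its energy from fat, with or without injections of CMPF, a furan fatty acid metabolite that circulates in blood. In the prevention model, mice received vehicle or CMPF (6 mg/kg per day) for 1 week before 4 weeks of HFD per the sample labels (4-5 weeks in the series text). In the reversal model, mice were on HFD for 6 weeks and then received vehicle or CMPF at the same dose for 2 weeks. Each model had a chow, an HFD and an HFD with CMPF group of 3 arrays, 18 arrays in all. Replicates 2 and 3 of the prevention CMPF group were nearly identical and were counted as 1 sample, so that group has n = 2. On every array Xist was low (3.80 to 5.25 on the log2 scale) and the Y-linked gene Eif2s3y was high (8.48 to 9.24).

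Signs of RNA quality differed between groups. The 3' to 5' index of control transcripts, which is higher where RNA is shorter, was 1.43 ± 0.512 (SD, n = 3) in prevention chow and 2.84 ± 0.303 (SD, n = 3) in prevention HFD. This difference of 1.42 had an exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 allow. The index was 2.95 ± 0.285 (SD, n = 2) in prevention CMPF, 3.15 ± 0.566 (SD, n = 3) in reversal chow, 2.62 ± 0.969 (SD, n = 3) in reversal HFD and 2.63 ± 0.957 (SD, n = 3) in reversal CMPF. The exact p of the other comparisons was 0.6 for CMPF in prevention, 0.6 for HFD in reversal and 1 for CMPF in reversal. Reversal chow 2 stood apart from the other arrays of its model, with a median correlation of 0.948 with them and a beta-actin signal of 10.46 on the log2 scale.

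**Figure D1:**
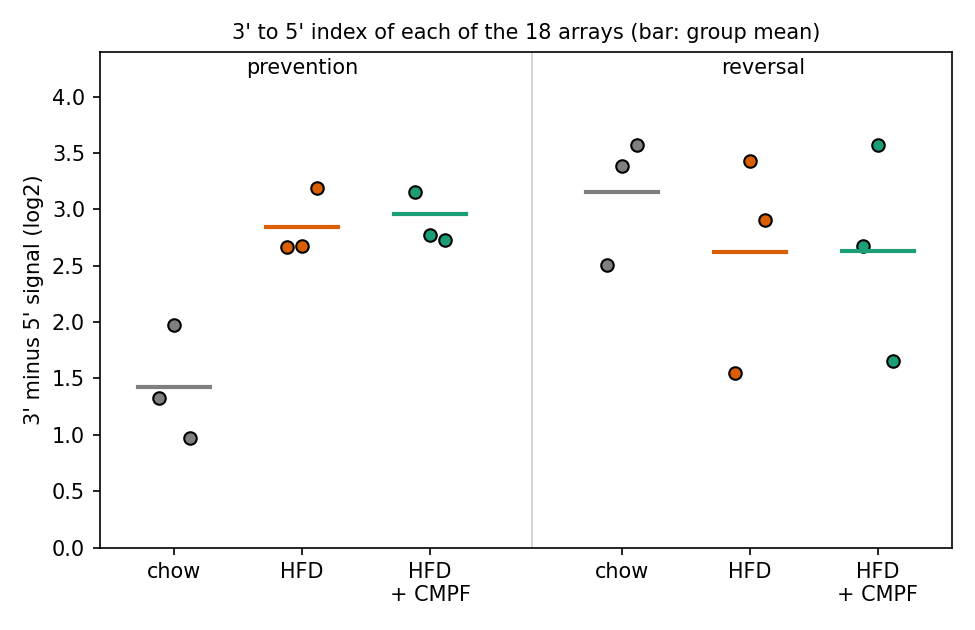
The 3' to 5' index (log2, vertical axis) of each of the 18 arrays (points) by group, with the mean of each group (bars; the near-identical prevention CMPF arrays 2 and 3 enter their mean as 1 sample). The 3 prevention chow arrays lie lower than the other 6 prevention arrays.

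The first comparison asked what HFD did to the liver of vehicle-injected mice in the prevention model (n = 3 against 3). The cytochromes P450 Cyp2b9 and Cyp2b13, which are female-biased in mouse liver, rose by 3.68 ± 0.561 (log2 fold change ± SE, adjusted p = 0.0105) and 3.35 ± 0.648 (0.0178). Cd36, the fatty acid translocase, rose by 2.25 ± 0.512 (adjusted p = 0.0291), from a mean log2 signal of 6.43 ± 0.166 to 8.68 ± 1.05 (SD). Vldlr, the receptor of very low density lipoprotein, rose by 1.83 ± 0.488 (adjusted p = 0.0449) and Plin4, a lipid droplet coat protein, by 1.71 ± 0.392 (0.0293). The largest falls were those of Fabp5, a fatty acid binding protein (-2.97 ± 0.657, adjusted p = 0.0261), and Ugt2b38, a male-biased glucuronosyltransferase (-2.97 ± 0.432, 0.00931). The 3' to 5' index was higher in the HFD group by 1.42.

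Of 13221 genes, 737 passed in this comparison: 230 rose and 507 fell, with 43 raised and 150 lowered more than 2-fold. Slc13a3, a dicarboxylate transporter, rose by 2.02 ± 0.421 and Ppbp, a platelet chemokine precursor, by 2.02 ± 0.479. Gstm3, a glutathione transferase (1.95 ± 0.472), Lgals1, galectin 1 (1.91 ± 0.494), and Themis, a T-cell signalling protein (1.75 ± 0.361), rose as well. The adjusted p of these 5 genes was 0.0209 to 0.0405. Got1, the cytosolic aspartate aminotransferase (-2.04 ± 0.47), Serpina12, vaspin (-1.88 ± 0.434), Fmn2, an actin nucleator (-1.85 ± 0.395), and Cldn1, a tight junction protein (-1.83 ± 0.379), fell. So did Cyp2c68, a cytochrome P450 (-1.83 ± 0.299), C6, a complement component (-1.82 ± 0.277), Prr16 (-1.81 ± 0.392) and Hsd3b5, a male-specific steroid dehydrogenase (-1.78 ± 0.435). The adjusted p of these 8 genes was 0.0105 to 0.0331. Of the genes given in every comparison, Cpt1a, the carnitine palmitoyltransferase of mitochondrial fatty acid uptake, fell by 0.96 ± 0.14 (adjusted p = 0.00931). Pck1, the rate-limiting enzyme of gluconeogenesis, fell by 1.11 ± 0.284 (0.0393). The values of Fgf21 (-1.22 ± 0.435, adjusted p = 0.106), G6pc (-1.12 ± 0.389, 0.1) and Pparg (0.63 ± 0.176, 0.0511) did not pass. Nor did Srebf1 (-0.01 ± 0.335, 0.991), Fasn (0.22 ± 0.262, 0.642), Acaca (0.20, 0.399), Acacb (0.46, 0.379), Scd1 (-0.10 ± 0.821, 0.957) or Ppara (-0.21, 0.591).

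Of the 40 gene lists, 5 passed for HFD in prevention and 13 had an unadjusted p under 0.05. Of 16 genes of polyunsaturated fatty acid and eicosanoid metabolism, 3 fell and 13 did not pass (4 fell adjusted over the list alone; median -0.515, fry adjusted p = 0.00539; adjusted p = 0.26 with an estimated correlation, the highest of its alternatives, from 0.00178). They were Elovl2, which elongates polyunsaturated fatty acids (-1.39 ± 0.182), Ephx2, the soluble epoxide hydrolase (-0.64 ± 0.111), and Fads2, the delta-6 desaturase (-0.49 ± 0.118). Cyp2j5, an epoxygenase, was at -0.76 (adjusted p = 0.0524). Of 16 male-biased liver genes, 8 fell (10 adjusted over the list alone; median -0.696, adjusted p = 0.00718; adjusted p = 0.26 with an estimated correlation, the highest of its alternatives, from 3.17e-07). Among them were C6, Ugt2b38, the bile acid and steroid transporter Slco1a1 (-1.19 ± 0.213) and the complement component C8b (-1.28 ± 0.247). Of 13 female-biased liver genes, 4 rose (6 adjusted over the list alone; median 0.278, mean 0.95, adjusted p = 0.00718; adjusted p = 0.26 with an estimated correlation, the highest of its alternatives, from 0.00263). The 4 were Cyp2b9, Cyp2b13, Cd36 and Fmo2, a flavin monooxygenase (0.91 ± 0.201). Of 16 genes of gluconeogenesis and glycogen, Pck1 fell (6 fell adjusted over the list alone; median -0.404, adjusted p = 0.00885; adjusted p = 0.26 with an estimated correlation, the highest of its alternatives, from 0.00263). Slc2a2, the hepatic glucose transporter, was at -0.84 (0.0608) and Fbp1, fructose bisphosphatase, at -0.64 (0.0757). Of 10 periportal zone genes, Pck1 and Cyp2f2, a periportal cytochrome P450 (-0.93 ± 0.136), fell (1 rose and 4 fell adjusted over the list alone; median -0.814, adjusted p = 0.0338; adjusted p = 0.513 with an estimated correlation, the highest of its alternatives, from 0.00599).

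The calls of all 5 lists in prevention were thus lost in camera with a correlation estimated for each list. The periportal call was also lost without chow 1 (adjusted p = 0.165), chow 3 (0.105), HFD 1 (0.0665), HFD 2 (0.119) or HFD 3 (0.0591) and with the replicate block (0.0573). With the index as a covariate 2 lists passed, the female-biased and the male-biased list (0.00784 each). Below the list threshold, 4 of 18 genes of the unfolded protein response of the endoplasmic reticulum fell (11 adjusted over the list alone; median -0.715, list adjusted p = 0.0601). Manf, an endoplasmic reticulum stress factor, was at -1.58 ± 0.316 (adjusted p = 0.0179) and Pdia6, a disulfide isomerase, at -1.19 ± 0.311 (0.041). Of 19 lipid droplet genes and PPAR gamma targets, 5 rose (6 adjusted over the list alone; list adjusted p = 0.102), among them Cd36 and Mogat1, a monoacylglycerol acyltransferase (1.59 ± 0.289, adjusted p = 0.0157). Of 32 genes of fatty acid oxidation, 5 fell (1 rose and 6 fell adjusted over the list alone; list adjusted p = 0.22), among them Cpt1a and Hadhb of the mitochondrial trifunctional protein (-1.29 ± 0.2, 0.0113). With the mean of a gene's probe sets, Hadhb was at -0.37 (adjusted p = 0.0806), Vldlr at 0.93 (0.0597), Serpina12 at -1.05 (0.067), Pdia6 at -0.76 (0.122), Fads2 at -0.28 (0.248) and Cyp2j5 at -0.12 (0.52). Cpt1a (-0.50) and Fmo2 (0.60) passed at smaller values, as did Gstm3. With the index as a covariate Cldn1 was at -1.08, Prr16 at -0.88, Pck1 at -0.59 and Hadhb at -0.85. Without chow 1 and 3, Fmn2 was at -0.74, Slco1a1 at -0.74 and Plin4 at 1.03. The count of genes depended on single arrays and on the index. It was 12 without chow 1, 1624 without chow 2, 8 without chow 3, 25 without HFD 1, 114 without HFD 2 and 242 without HFD 3. The count was 17 with the index as a covariate. Leaving out chow 1 and 3 leaves 1 chow array, so calls lost there cannot show a dependence on the index.

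The same question was asked in the reversal model, where vehicle-injected mice had 6 weeks of HFD before the injections (n = 3 against 3). Cyp2b9 rose by 5.19 ± 0.561 (adjusted p = 0.000765), from a mean log2 signal of 5.26 ± 1.22 to 10.45 ± 0.515 (SD), and Cyp2b13 rose by 3.40 ± 0.648 (0.0181). Thrsp, a lipogenic nuclear protein, rose by 3.60 ± 0.396 (adjusted p = 0.000765) and Cd36 by 3.23 ± 0.512 (0.00751). Msmo1 and Sqle, enzymes of cholesterol synthesis, rose by 3.72 ± 0.685 (0.0153) and 3.03 ± 0.618 (0.0227). Pparg, the lipogenic nuclear receptor, rose by 1.72 ± 0.176 and Mogat1 by 2.64 ± 0.289 (adjusted p = 0.000765 for both). The acute phase genes Orm2 and Saa1 rose by 3.78 ± 0.858 (0.0356) and 3.28 ± 0.732 (0.0331).

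Of 13221 genes, 324 passed in reversal: 287 rose and 37 fell, with 108 raised and 6 lowered more than 2-fold. Hao2, a peroxisomal hydroxyacid oxidase (3.70 ± 0.682, adjusted p = 0.0155), and Lgals1 (2.97 ± 0.494, 0.0105) also rose. The largest falls were those of Cyp4a31, a fatty acid omega-hydroxylase (-2.20 ± 0.537, 0.0472), Ctcflos (-2.14 ± 0.43, 0.0221) and Fmn2 (-2.02 ± 0.395, 0.0201). Lpl, lipoprotein lipase, fell by 1.98 ± 0.434 (0.0306) and Plin5, a lipid droplet protein, fell by 1.26 ± 0.311 (0.0496). Zfp707 fell, as did Tsks (-0.95), Ganc (-0.93), Nrbp2 (-0.85) and Id4, an inhibitor of DNA binding (-0.83). Of the genes given in every comparison, Fasn, the fatty acid synthase, rose by 1.08 ± 0.262 (adjusted p = 0.0469). Srebf1 (0.89, adjusted p = 0.152), Fgf21 (-0.66), Acaca (-0.14), Acacb (-0.09), Scd1 (-0.39), Cpt1a (0.05), Ppara (0.10), Pck1 (-0.68) and G6pc (-1.03) did not pass.

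Of the 40 gene lists, 6 passed for HFD in reversal, all upward, and 12 had an unadjusted p under 0.05. Of 12 pericentral zone genes, 5 rose (8 adjusted over the list alone; median 0.735, adjusted p = 0.000308; adjusted p = 0.196 with an estimated correlation, the highest of its alternatives, from 1.61e-05). Among them were Gulo (0.88 ± 0.0995), Lect2, a secreted hepatokine (1.87 ± 0.211), Slc13a3 (2.44 ± 0.421) and Lgr5, the R-spondin receptor (0.91 ± 0.188). Of 18 genes of cholesterol synthesis and uptake, 6 rose (13 adjusted over the list alone; median 1.00, adjusted p = 0.031; adjusted p = 0.616 with an estimated correlation, the highest of its alternatives, from 9.58e-07), including Msmo1, Sqle, Nsdhl (1.74, adjusted p = 0.0201) and Cyp51 (2.33, 0.0284). Of 23 lipogenic genes, 5 rose (6 adjusted over the list alone; median 0.356, adjusted p = 0.0266; adjusted p = 0.616 with an estimated correlation, the highest of its alternatives, from 0.0063), including Thrsp, the oxysterol receptor Nr1h3 (0.61, 0.0242), Insig1 (1.62, 0.0383) and Fasn. Of 19 lipid droplet genes and PPAR gamma targets, 5 rose and Lpl and Plin5 fell (the same numbers adjusted over the list alone; median 0.312, adjusted p = 0.0436; adjusted p = 0.616 with an estimated correlation, the highest of its alternatives, from 0.0176), with Pparg, Mogat1 and Cd36 among the 5. Of 17 genes of xenobiotic metabolism, 3 rose (5 adjusted over the list alone; median 0.46, adjusted p = 0.0266; adjusted p = 0.616 with an estimated correlation, the highest of its alternatives, from 0.00218), including Cyp2b9, Cyp2b13 and Cyp2c50 (0.54, 0.0284). Of 13 female-biased liver genes, 4 rose (4 adjusted over the list alone; adjusted p = 0.0266; adjusted p = 0.666 with an estimated correlation, the highest of its alternatives, from 0.00047). The list went up by the fry test and its mean (1.07), while its median was -0.089. Cyp2b9, Cyp2b13, Hao2 and Cd36 were the members that rose.

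The calls of all 6 lists in reversal were thus lost in camera with a correlation estimated for each list. Quantile normalisation ended the lipogenesis (0.239), cholesterol (0.0881), lipid droplet (0.0881) and female-biased calls (0.0536), and cyclic loess the first 3 of these (0.156, 0.0755 and 0.0755). The index as a covariate, a fit on the 6 arrays compared and the leaving out of HFD 1 and CMPF 3 each ended every call but the pericentral one (adjusted p from 0.0525 to 0.223), and a fit on the reversal arrays alone ended 4. The replicate block ended the cholesterol call (0.0513) and the preset correlation the female-biased one (0.351). The pericentral call held without each array in turn. The other 5 calls were each lost without 2 to 4 single arrays among chow 1, chow 2, chow 3, HFD 1 and HFD 3, with adjusted p from 0.0541 to 0.16. Below the list threshold, 3 of 24 acute phase genes rose (8 adjusted over the list alone; list adjusted p = 0.0612), with Saa4 at 1.06 (adjusted p = 0.0121). Of 18 circadian clock genes, 4 rose and 1 fell (6 and 1 adjusted over the list alone; list adjusted p = 0.138), with Bhlhe40 at 1.45 (0.00569) and Ciart at 1.04 (0.00751). With the mean of a gene's probe sets Lgr5 was at 0.43 (adjusted p = 0.0833) and Saa4 at 1.72 (0.0173), while Cyp2c50 was at 0.34 with quantile normalisation and 0.35 with cyclic loess. All 18 genes of the unfolded protein response had positive values and 0 passed by limma (0 adjusted over the list alone; median 0.482, list adjusted p = 0.137). The count of genes was 577 without chow 1, 135 without chow 2, 195 without chow 3, 99 without HFD 1, 154 without HFD 2 and 142 without HFD 3. It was 38 in a fit on the reversal arrays alone, 0 in a fit on the 6 arrays compared and 86 without HFD 1 and CMPF 3.

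HFD raised 24 of the same genes in both models, against 4.99 expected if the calls were independent, among them Cyp2b9, Cyp2b13, Cd36, Slc13a3, Lgals1, Themis, Cyp2c38 and Mogat1. It lowered 3 genes in both (1.42 expected): Fmn2, Chrna2 and Atrn. A further 9 genes fell in prevention and rose in reversal (11 expected), and 0 did the reverse (0.644 expected). The calls of both models use the same spread for each gene, so they are not fully independent. Of the genes named here, only Cyp2b9 and Chrna2 kept their prevention call with the index as a covariate.

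**Figure D2:**
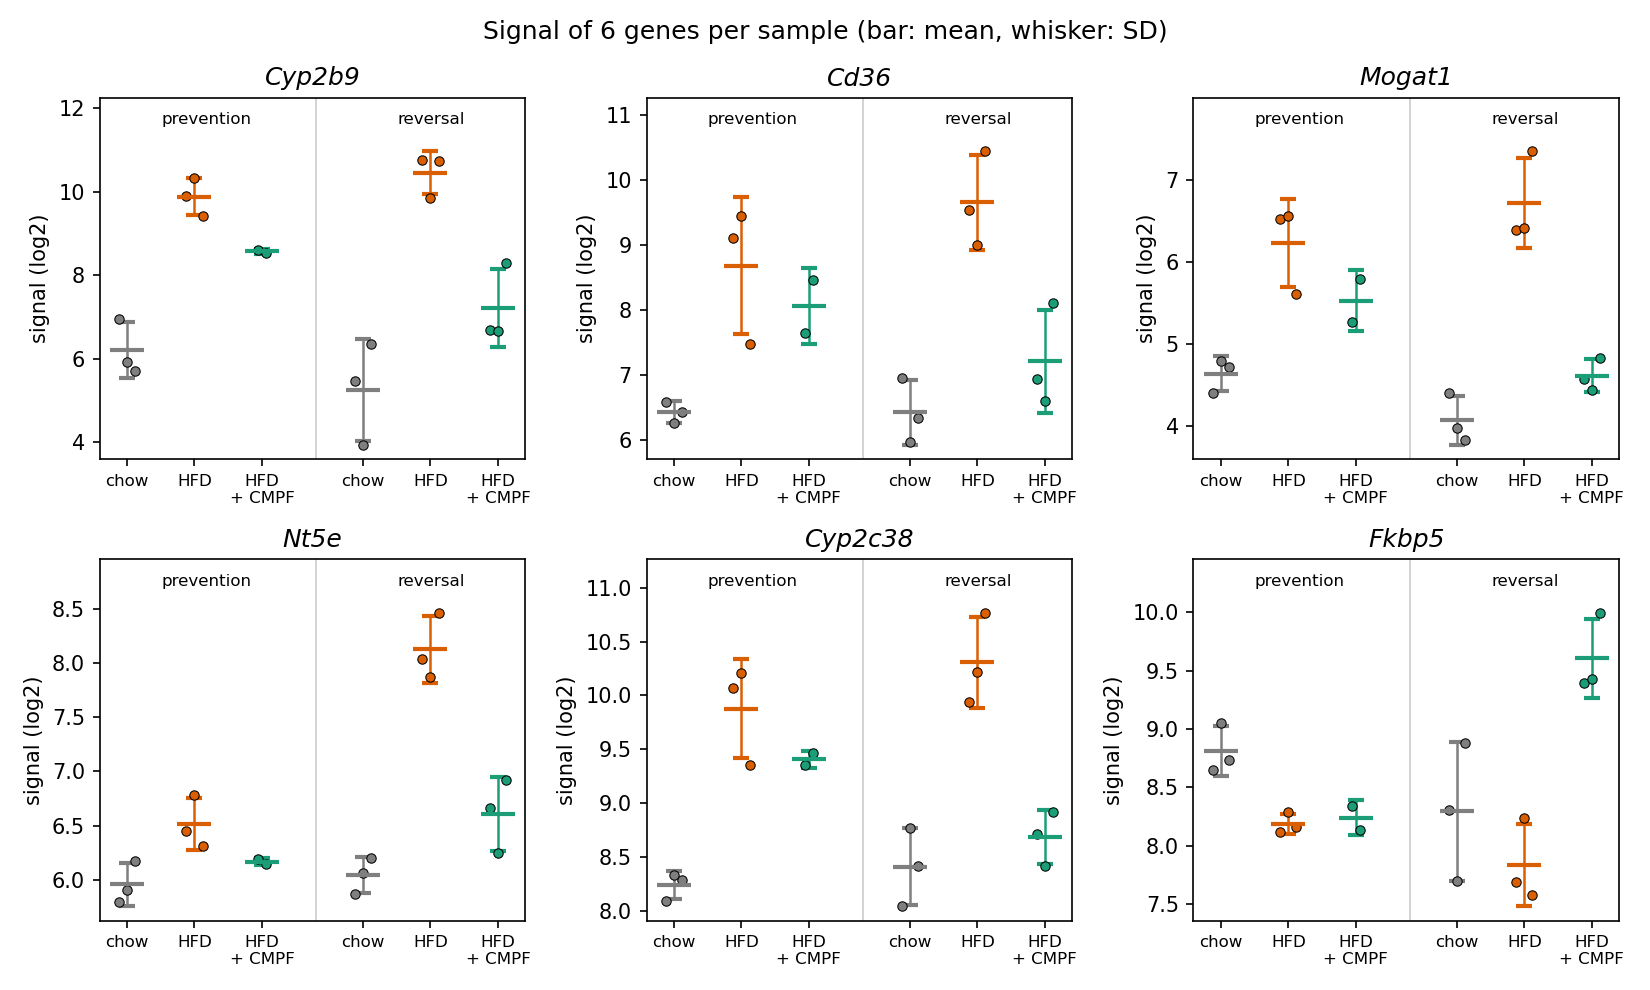
Log2 signal (vertical axes) of 6 genes in each sample (points) by group, with the mean (bar) and SD (whisker) of each group; n = 3, and n = 2 in prevention CMPF. In reversal, Mogat1, Nt5e and Cyp2c38 lie higher in HFD than in HFD with CMPF, with no overlap of samples, and Fkbp5 lies lower.

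The prevention model then asked whether CMPF given before the diet changed the liver on HFD (n = 2 against 3). By limma, 0 of 13221 genes passed, and 1060 had an unadjusted p under 0.05, where 661.1 are expected by chance. Of the 1060, 775 were positive. The largest values among the genes given in every comparison were those of Fgf21, a hepatic fasting and stress hormone (2.04 ± 0.486, adjusted p = 0.274), Scd1, the stearoyl-CoA desaturase (-3.08 ± 0.918, 0.409), and Acacb, the acetyl-CoA carboxylase of mitochondria (-1.25 ± 0.342, 0.359). Scd1 ranged from -4.33 without CMPF 2 and 3 to -1.83 without CMPF 1, and its other probe set was at -1.44. The smallest p upward belonged to Sntb1, a syntrophin (0.90 ± 0.154, adjusted p = 0.188), Capn7, a calpain (0.72 ± 0.124, 0.188), and Ccdc47 (0.70 ± 0.125, 0.215), and downward to Tmem120a (-1.03 ± 0.16, 0.188), Ttc39a (-1.09 ± 0.199, 0.215) and Cenpm, a centromere protein (-0.96 ± 0.212, 0.252). The values of Srebf1 (0.27), Fasn (-0.34), Acaca (-0.16), Cpt1a (0.11), Ppara (-0.13), Pparg (0.33), Cd36 (-0.62), Pck1 (0.63) and G6pc (-0.06) did not pass either.

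Of the 40 gene lists, 0 passed fry for CMPF in prevention, and 6 had an unadjusted p under 0.05. The female-biased liver genes had 12 of 13 negative values (median -0.409, adjusted p = 0.0884; 0 fell adjusted over the list alone), with Cyp2b13 at -2.14 ± 0.724 and Fmo2 at -0.64. The male-biased genes had a median of 0.399 (adjusted p = 0.149; 7 of 16 rose adjusted over the list alone), with C6 at 1.34 ± 0.309 and Ugt2b1, a glucuronosyltransferase, at 0.85. The targets of ATF4, the transcription factor of the integrated stress response, had a median of 0.259 (adjusted p = 0.104; 3 of 15 rose adjusted over the list alone), with the transcription factor Atf5 at 1.44 ± 0.329 and the mitochondrial folate enzyme Mthfd2 at 0.40. All 18 genes of the unfolded protein response were positive (median 0.726, adjusted p = 0.19; 9 rose adjusted over the list alone), with the disulfide isomerase Pdia4 at 1.21 ± 0.339 and the chaperone Hsp90b1 at 0.74 ± 0.195. With all 18 arrays counted separately 36 genes and 1 list passed. With array weights 98 genes and 3 lists passed, and without HFD 3, 1 gene and 2 lists. Adjusted p ranged over the alternatives from 9.09e-05 to 0.449 for the female-biased list and from 1.1e-08 to 0.563 for the unfolded protein response.

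CMPF-treated mice on HFD were also compared with chow mice in prevention (n = 2 against 3). The ATF4 target genes rose as a list: all 15 were positive (median 0.301, fry adjusted p = 0.00299). Sesn2, a stress-induced regulator of mTORC1, was at 0.62 ± 0.14 and Eif4ebp1, a translation repressor, at 0.52 ± 0.123. With the mean of a gene's probe sets these were at 0.27 and 0.042. Of the 15, 0 passed over all genes by limma and 2 rose adjusted over the list alone. The pericentral zone genes rose as a list, with 11 of 12 positive (median 0.498, adjusted p = 0.0301; adjusted p = 0.169 with an estimated correlation, 0.000135 to 0.35 over its alternatives). Glul, glutamine synthetase, was at 0.53 ± 0.131 and Slc13a3 at 1.51 ± 0.47. Of the 12, 0 passed over all genes and 2 rose adjusted over the list alone. By limma 0 of 13221 genes passed, with 1321 at an unadjusted p under 0.05. The ATF4 call held with an estimated correlation (adjusted p = 0.0423; 4.88e-05 to 0.171 over its alternatives). It was lost without CMPF 1 (0.105), with the index as a covariate (0.0778), without chow 1 and 3 (0.12) and in fits on the prevention arrays alone (0.0518) or on the arrays compared (0.171). The pericentral call was lost in the same fits (0.0531 and 0.0813), with quantile normalisation (0.0902), cyclic loess (0.114), the replicate block (0.0571) or the index as a covariate (0.111), without chow 1 and 3 (0.35), and without chow 2 (0.0679), chow 3 (0.103), CMPF 1 (0.276) or CMPF 2 and 3 (0.138). The index was 1.43 in the chow and 2.95 in the CMPF group.

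The reversal model asked whether CMPF given after 6 weeks of HFD changed the liver (n = 3 against 3). Of 13221 genes, 5 passed, 2 upward and 3 downward. Mogat1, which makes diacylglycerol from monoacylglycerol, fell by 2.10 ± 0.289 (adjusted p = 0.0271), from 6.71 ± 0.545 to 4.62 ± 0.2 (mean log2 signal ± SD), where chow mice had 4.08 ± 0.298. Nt5e, the ecto-5'-nucleotidase CD73, fell by 1.52 ± 0.192 (0.0199) and Cyp2c38, a cytochrome P450 of arachidonic acid metabolism, fell by 1.63 ± 0.249 (0.0381). Fkbp5, a cochaperone of the glucocorticoid receptor that glucocorticoids induce, rose by 1.77 ± 0.259 (0.0353). The 3 genes that fell had risen with HFD: Mogat1 as given, Nt5e by 2.08 ± 0.192 (adjusted p = 0.000429) and Cyp2c38 by 1.90 ± 0.249 (0.00311). That comparison shares the HFD arrays. The other probe set of Nt5e was at -0.0255 with CMPF in reversal and that of Fkbp5 at 0.23. With the mean of a gene's probe sets Nt5e was at -0.77 (adjusted p = 0.0709) and Fkbp5 at 1.00 (0.0771).

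At unadjusted p under 0.05 there were 634 genes for CMPF in reversal, where 661.1 are expected by chance. In the upward direction the next named gene was Ptgis, prostacyclin synthase (0.77 ± 0.137, adjusted p = 0.0903). Genes that HFD had raised had negative values that did not pass: Cd36 (-2.44 ± 0.512, 0.17), Pparg (-0.94 ± 0.176, 0.0992) and Cyp2b9 (-3.24 ± 0.561, 0.0858). Scd1 was at -2.81 ± 0.821 (0.569). Fgf21 (-0.45), Srebf1 (-0.06), Fasn (-0.11), Acaca (-0.02), Acacb (-0.19), Cpt1a (-0.02), Ppara (0.23), Pck1 (0.95) and G6pc (0.77) did not pass. The 4 named genes that CMPF changed in reversal had CMPF effects in prevention (n = 2 against 3) of -0.70 ± 0.323 (Mogat1), -0.35 ± 0.214 (Nt5e), -0.47 ± 0.278 (Cyp2c38) and 0.05 ± 0.289 (Fkbp5). Of the 4, 0 differed between models by limma (adjusted p from 0.329 to 0.507).

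Of the 40 gene lists, 0 passed fry for CMPF in reversal, and 7 had an unadjusted p under 0.05. The female-biased genes were lowest in p (adjusted p = 0.0591; mean -0.975, median -0.077, 9 of 13 negative; 4 fell adjusted over the list alone), with Cyp2b9 and Cyp2b13 (-3.54 ± 0.648) as examples. At an adjusted p of 0.0768 stood the pericentral genes (11 of 12 negative, median -0.441; 3 fell adjusted over the list alone), with Lgr5 at -0.73 (-0.38 with the mean of its probe sets) and Oat at -0.73. The lipid droplet genes had the same value (15 of 19 negative, median -0.434; 4 fell adjusted over the list alone), with Mogat1 and Pparg. So had the genes of the glucocorticoid and fasting response (12 of 16 positive, median 0.853; 4 rose adjusted over the list alone), with Fkbp5 and Zbtb16, a glucocorticoid-induced transcription factor (2.52 ± 0.574, 0.266). The clock genes stood there too (14 of 18 positive, median 0.354; 5 rose adjusted over the list alone), with Ciart at 0.86 and Usp2 at 1.15. The polyunsaturated fatty acid list had an adjusted p of 0.0898 (median -0.186; 2 fell adjusted over the list alone), with Elovl5 at -0.81 and Cyp2c23, an epoxygenase, at -2.22. The count of 5 genes became 0 without HFD 3 or CMPF 2 and 1 without CMPF 1 or CMPF 3. Mogat1, Nt5e, Cyp2c38 and Fkbp5 all lost their call without CMPF 1, while Nt5e kept its call without CMPF 3. The count was 3 without HFD 1 and CMPF 3, of which 1, Nt5e, was among the 5. The count was 0 in fits on the reversal arrays alone and with the mean of a gene's probe sets, and 17 with the index as a covariate.

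**Figure D3:**
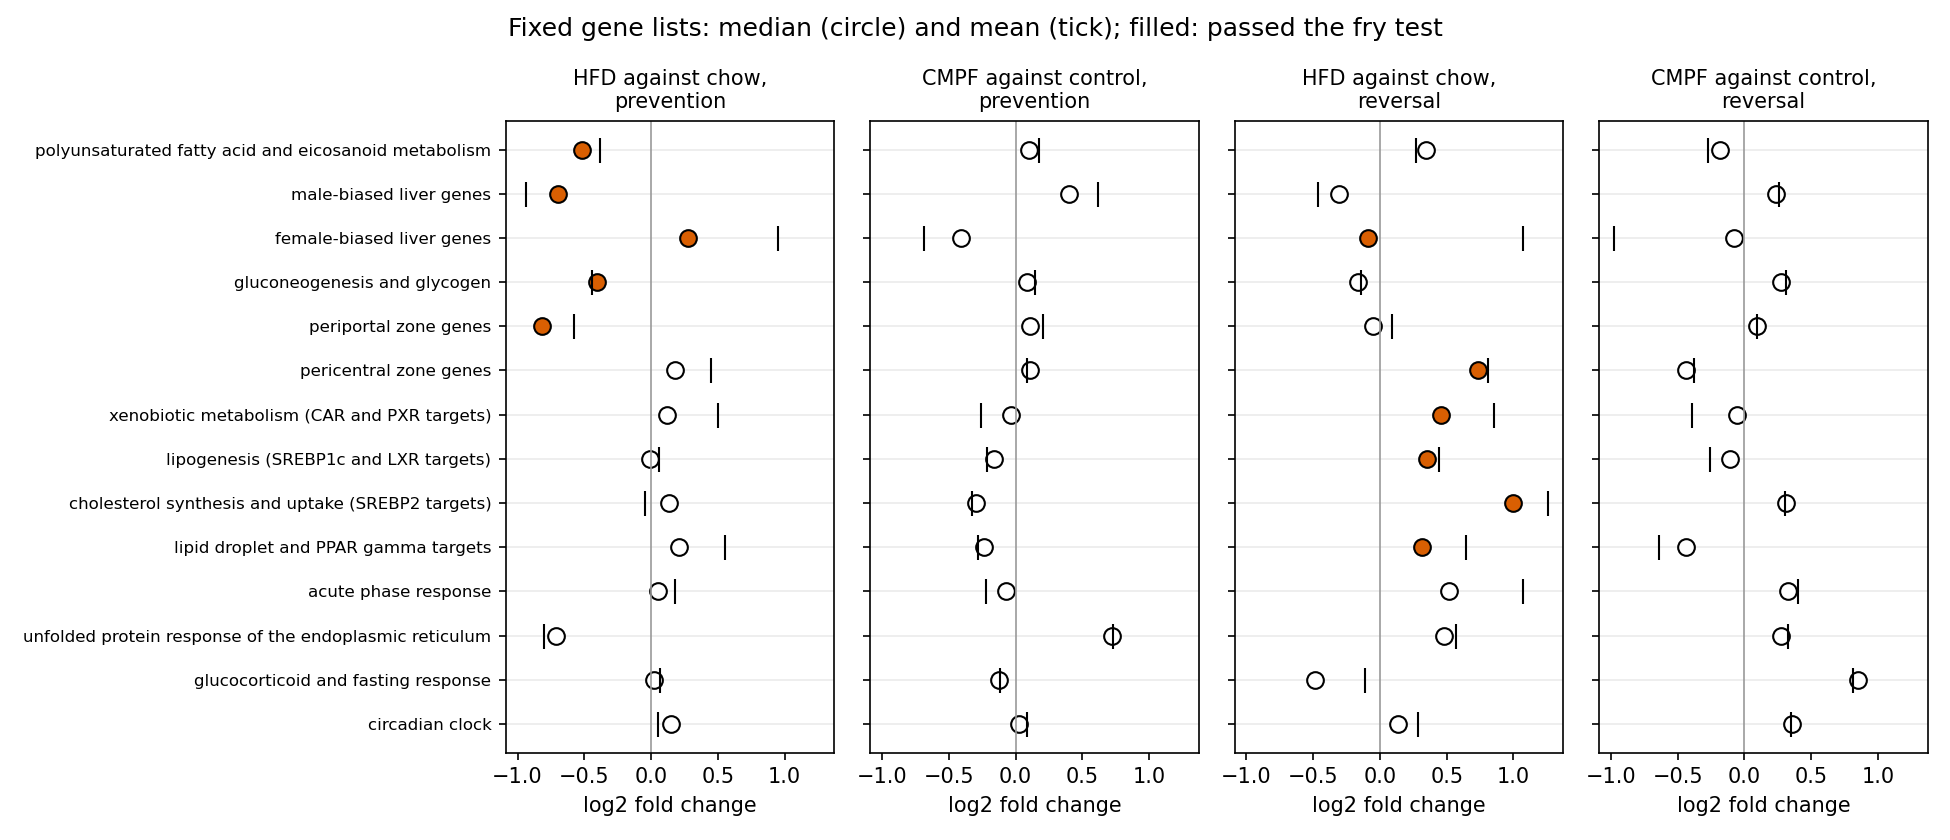
Median (circle) and mean (tick) log2 fold change (horizontal axes) of the members of 14 fixed gene lists in the 4 comparisons; filled circles passed the fry test. The lists that passed are in the HFD panels, 5 in prevention and 6 in reversal, and the unfolded protein response has medians of -0.715 with HFD and 0.726 with CMPF in prevention.

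CMPF-treated mice on HFD still differed from chow mice in reversal (n = 3 against 3). Clock genes rose as a list (7 of 18 rose and 1 fell; 10 rose and 2 fell adjusted over the list alone; median 0.744, adjusted p = 0.00895; adjusted p = 0.549 with an estimated correlation, from 0.000222 over its alternatives). The clock repressor Ciart was at 1.90 ± 0.164 (adjusted p = 0.000164) and the clock-controlled Usp2 at 2.12 ± 0.225 (0.00042). Both are evening genes of the clock, while Arntl, a morning gene, was among the genes lower than in chow mice. A difference in time of day between these groups was not tested. Genes of cholesterol synthesis rose (8 of 18; 16 adjusted over the list alone; median 1.37, adjusted p = 0.0116; adjusted p = 0.549 with an estimated correlation, from 8.71e-13 over its alternatives), with Msmo1 at 4.05 ± 0.685 and Sqle at 3.46 ± 0.618. Acute phase genes rose (7 of 24; 14 adjusted over the list alone; median 0.938, adjusted p = 0.0204; adjusted p = 0.549 with an estimated correlation, from 3.7e-10 over its alternatives), with Saa2 at 5.38 ± 1.01 and Saa1 at 4.27 ± 0.732. Pericentral genes passed (2 of 12 rose; 3 rose and 1 fell adjusted over the list alone; median 0.311, adjusted p = 0.0204; adjusted p = 0.659 with an estimated correlation, from 3e-04 over its alternatives), with Gulo at 0.83 ± 0.0995 and Lect2 at 1.36 ± 0.211. Genes of the unfolded protein response passed too (1 of 18 rose, Herpud1 at 1.52 ± 0.365; 10 adjusted over the list alone; median 0.852, adjusted p = 0.0313; adjusted p = 0.549 with an estimated correlation, from 1.34e-07 over its alternatives).

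Of 13221 genes, 265 passed between CMPF-treated and chow mice in reversal, 213 upward and 52 downward. Of the genes that CMPF changed, Fkbp5 (1.31 ± 0.259, adjusted p = 0.0205) was above chow, while Mogat1 (0.54, 0.341), Cyp2c38 (0.27, 0.584) and Nt5e (0.56, 0.145) did not pass. All 5 list calls were thus lost in camera with an estimated correlation. Quantile normalisation (0.167) and cyclic loess (0.26) ended the pericentral call, and array weights (0.113) that of the unfolded protein response, where Herpud1 was at 0.60. A fit on the 6 arrays compared ended these 2 calls (0.0748 and 0.265), and the replicate block those of the acute phase (0.0537) and the unfolded protein response (0.106). A fit on the reversal arrays alone ended the pericentral, acute phase (0.0517 each) and unfolded protein response calls (0.184), and without HFD 1 and CMPF 3 every call but that of the clock was lost (0.0778 each). The calls of the acute phase, pericentral and unfolded protein response lists were lost without CMPF 1 or CMPF 3, and 1 or more of them without chow 1, chow 2, chow 3 or CMPF 2 (adjusted p from 0.061 to 0.121). The count of genes was 138 without chow 2, 104 without CMPF 1, 73 without CMPF 3 and 71 without HFD 1 and CMPF 3.

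The effects were then compared between models (reversal minus prevention). For HFD, 1453 genes differed, 1169 higher and 284 lower in reversal, and the 3' to 5' index moved by 1.42 with HFD in prevention and by -0.529 in reversal. The genes with the largest differences upward were Msmo1 (4.66 ± 0.968, adjusted p = 0.0202) and Fdps (3.03 ± 0.796, 0.0326) of cholesterol synthesis. Gsdme, a gasdermin (3.21 ± 0.895, 0.0385), Prr16 (3.03 ± 0.554, 0.018) and Tuft1 (2.92 ± 0.593, 0.0194) were the others. Downward they were Ctcflos (-2.62 ± 0.609, 0.0263), Ppbp (-2.52 ± 0.677, 0.0346) and Chka, a choline kinase (-2.29 ± 0.63, 0.0368). Pdk4, a kinase of pyruvate dehydrogenase (-2.23 ± 0.573, 0.0311), and Mfsd2a, a lysophospholipid transporter (-2.13 ± 0.562, 0.0328), followed. The HFD effect was higher in reversal over 16 genes of polyunsaturated fatty acid metabolism (4 higher, 12 not passing; 9 higher and 1 lower adjusted over the list alone; median 0.746, adjusted p = 0.0027; adjusted p = 0.821 with an estimated correlation, the highest of its alternatives, from 0.000872), with Elovl2 at 1.18 ± 0.257 and Acsl4 at 1.87 ± 0.42. It was also higher over the 18 genes of the unfolded protein response (10 higher; 11 adjusted over the list alone; median 1.31, adjusted p = 0.0464; adjusted p = 0.832 with an estimated correlation, the highest of its alternatives, from 1.61e-05), with Manf at 2.15 ± 0.447 and Pdia4 at 1.98 ± 0.429. Of the 40 lists, 14 had an unadjusted p under 0.05. With the index as a covariate the differences were 1.11 (Gsdme), 1.87 (Fdps), 1.76 (Prr16), 0.74 (Elovl2), -1.61 (Ctcflos) and -0.78 (Chka). Both list calls were lost there (0.123 and 0.138). The unfolded protein response call was also lost with quantile normalisation (0.0544), array weights (0.0774), the replicate block (0.126) and without reversal HFD 1 and CMPF 3 (0.107).

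The count of 1453 was 0 with the index as a covariate and 217 without reversal HFD 1 and CMPF 3. Without single arrays it was 0 (prevention chow 1), 2354 (prevention chow 2), 35 (prevention chow 3), 260 (prevention HFD 3), 777 (prevention HFD 1), 743 (prevention HFD 2), 2400 (reversal chow 1), 633 (reversal chow 2), 788 (reversal chow 3) and 55 (reversal HFD 1). The call of the unfolded protein response was lost without prevention chow 1, chow 3, HFD 2 or HFD 3 or reversal chow 1, chow 2, HFD 1 or HFD 2, with adjusted p from 0.058 to 0.108. Subtraction of array medians moved the median effect of all genes from 0.0309 to 0.17. For CMPF, 0 genes differed by limma (1048 at an unadjusted p under 0.05), and 0 of the 40 lists differed by fry (3 unadjusted). Downward, the genes with the smallest p were Sntb1 (-1.30 ± 0.207, adjusted p = 0.262), Mreg, melanoregulin (-1.33 ± 0.226, 0.262), and Slc16a1, a monocarboxylate transporter (-1.55 ± 0.278, 0.304). Upward, low p belonged to Ptgis (1.06 ± 0.205, 0.313) and Tspan4, a tetraspanin (0.73 ± 0.156, 0.319).

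Whether CMPF moved the genes that the diet moves was tested with sets from the other model, which shares no array. The moderated t that ranked the sets does use the spread of all samples, those of the model tested included. In the model tested, HFD itself moved these sets little. The median HFD effect in prevention was 0.145 over the genes raised in reversal and 0.0838 over those lowered. In reversal it was 0.111 over the genes raised in prevention and 0.149 over those lowered. Both lowered sets thus had the other sign, so a small CMPF median cannot show whether CMPF turns back the diet effect. Over the 100 genes that HFD raised most in reversal, the median CMPF effect in prevention was -0.00548 (fry adjusted p = 0.85), and over the 100 that it lowered most it was -0.0328 (0.85). Over the 100 genes that HFD raised most in prevention, among them Cyp2b9 and Mogat1, the median CMPF effect in reversal was -0.0621 (0.492; 69 of 100 negative), and over the 100 lowered most it was -0.0235 (0.85). By its p unadjusted for the 4 sets (0.123 by fry in the limma fit), the set raised in prevention passed with array medians subtracted (-0.127), the preset correlation (-0.0621), 50 genes (-0.101), the replicate block (-0.113), the index as a covariate (-0.156) or without prevention chow 1 and 3 (-0.0607). On leaving out 1 array its median was -0.171 (reversal HFD 1) to 0.00472 (reversal CMPF 3). The medians of the other 3 sets took either sign (-0.115 to 0.0417, -0.0682 to 0.0568 and -0.107 to 0.078). Across genes, the CMPF effects of the 2 models had r = -0.0179. Of the 10 splits of the 6 reversal arrays, 8 gave an r as large in size, and the largest of the other splits was 0.169. Without prevention HFD 3 this r was 0.0854. The HFD effects had r = -0.201, with 4 of 10 splits as large in size and 0.4 as the largest of the other splits. With the index as a covariate their r was 0.143. Within a model, the CMPF and HFD effects share the HFD arrays, so their correlation across genes (-0.626 in prevention, -0.369 in reversal) was set beside simulated data. With no effects these gave a mean of -0.41 (-0.942 to 0.767) and -0.47 (-0.93 to 0.875).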

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

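The tests of RNA integrity in this part were chosen after the result was seen, as were the index as a covariate and the leaving out of the arrays of lowest index; the splits of the samples were planned. The HFD effect differed between the reversal and the prevention model for 1453 genes by limma's test of the difference itself. The named genes had differences (reversal minus prevention) of 4.66 (Msmo1), 3.21 (Gsdme), 3.03 (Fdps), 3.03 (Prr16) and 2.92 (Tuft1), and of -2.62 (Ctcflos), -2.52 (Ppbp), -2.29 (Chka), -2.23 (Pdk4) and -2.13 (Mfsd2a). The unfolded protein response had a median difference of 1.31 and the genes of polyunsaturated fatty acid and eicosanoid metabolism had one of 0.746. In 100 draws of splits within each model, the real one included, 1 gave as many as 1453 genes, and the highest of the others gave 646; 3 of 100 gave as many as 2 lists, and the highest of the others gave 3. These splits mix HFD and chow arrays, so they ask whether HFD had no effect in either model, not whether its effects were equal. A diet effect also widens the spread within mixed groups, which lowers their counts. The splits therefore cannot exclude chance for a difference of the HFD effects. Nor do they exclude a property of the arrays that follows the groups.

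RNA integrity is such a property for the HFD effect of prevention and for its difference from reversal: the 3' to 5' index rose by 1.42 with HFD in prevention and its change differed between models by -1.95. Slopes on the index were taken within the reversal groups, where diet is constant, and had the sign that RNA integrity needs in 91.0% of the 1169 genes higher in reversal (5 of 100 shuffles of the index within groups gave as high a share, at most 92.4%), in 87.7% of the 284 lower genes (3 of 100, at most 89.4%) and in 82.2% of the 230 genes that HFD raised in prevention (3 of 100, at most 83.9%). In the 507 genes that HFD lowered in prevention the share was 88.8%, which 7 of 100 shuffles reached (at most 91.9%), so that for these genes the test cannot decide. Those slopes would give a median of 0.389 where 1.11 was observed for the genes higher in reversal, and -0.247 where -0.831 was observed for those lowered in prevention. The reversal arrays that gave the slopes also entered the choice of the genes whose HFD effect differed. The fold changes of the prevention genes share no array with the slopes. With the index as a covariate the 1453 differences all kept their sign but 0 passed (median size 1.06 before and 0.645 after; median SE over all genes 0.227 and 0.248), and the 737 prevention genes fell to 17, of which 13 were among the 737 (0.789 and 0.514; SE 0.161 and 0.177), since the effects shrank while the SE grew. RNA integrity may therefore account for part of both results, and the diet length and injections that differ between the models stay open as biological explanations that were not tested.

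Among the 13 genes that passed with and without the index were Cyp2b9 (4.37 with it), Fabp5 (-4.23), Elovl2, Ugt2b38, C6, C8b and Cyp7b1. For the other counts, the 10 splits of 6 arrays are too few for a share under 0.05. HFD in prevention gave 737 genes (highest other split 0) and 5 lists (highest other 1), and HFD in reversal gave 324 genes (highest other 1) and 6 lists (highest other 0). CMPF in reversal gave 5 genes (highest other 0) and 0 lists (0 in every split), and CMPF-treated against chow mice in reversal gave 265 genes (highest other 0) and 5 lists (highest other 1). Over the genes that HFD raised in prevention, the CMPF effect of -0.0621 in reversal was matched in size by 5 of the 10 splits (highest other 0.188), and over the genes it lowered, the -0.0235 was matched by 10 of the 10 (highest other 0.176).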

How the results depend on the processing

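The alternatives chosen after seeing the data were all 18 arrays counted separately, the index as a covariate, and the leaving out of the arrays of lowest index; the others were chosen before the data were examined. Of 4039 values of 200 named gene results, 3228 kept their direction and their side of the threshold, 652 were weaker, 104 stronger and 55 reversed; of the reversed, 0 had passed. At least 1 alternative moved 29 of the 106 named gene values that passed and 53 of the 94 that did not by over 1.5-fold or turned them. Of 792 values of 36 list results, 608 stayed, 133 were weaker, 51 stronger and 0 reversed. The signal over background limits dim genes, and leaving out 1 of 3 arrays changes the number of samples as well as their values; where it left a group with 1 sample, that sample was assumed to vary like the other groups. Every probe set kept the filter on dim probe sets and left out the control probe sets, and its counts are of probe sets, not genes. Fits on the arrays of 1 model or of 2 groups have fewer residual degrees of freedom and use the spread of those arrays alone. With the arrays of 1 model, the count rose for HFD in prevention and fell in reversal. Pairs of chow arrays differed with an SD over bright genes of 0.308 to 0.444 in prevention and 0.347 to 0.78 in reversal. The main fit shares 1 spread between the models, so the reversal calls may rest in part on the prevention arrays. A threshold of 0.10 and the larger number of probe sets change the counts by construction. For the other changed values the cause was not tested.

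For HFD against chow in prevention (737 genes), every probe set gave 1554, array weights 2022, the arrays of the model 1151, the arrays of the 2 groups 278, a threshold of 0.10 gave 1632, the index as a covariate 17, and leaving out chow 1 and 3 gave 2. Leaving out 1 array gave 8 (chow 3) to 1624 (chow 2). For CMPF on HFD in prevention (0 genes), quantile normalisation gave 1, cyclic loess 1, array weights 98 and all 18 arrays 36. Leaving out 1 sample gave 0 to 1 (HFD 3). For CMPF on HFD against chow in prevention (0 genes), array weights gave 193, all 18 arrays 6 and leaving out chow 1 and 3 gave 1. Leaving out 1 sample gave 0 to 1 (chow 1). For HFD against chow in reversal (324 genes), subtraction of array medians gave 551, array weights 1064, the arrays of the model 38, the arrays of the 2 groups 0, a threshold of 0.10 gave 879 and leaving out HFD 1 and CMPF 3 gave 86. Leaving out 1 array gave 99 (HFD 1) to 577 (chow 1).

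For CMPF on HFD in reversal (5 genes), the mean of a gene's probe sets gave 0, every probe set 1, quantile normalisation 3, cyclic loess 3, array weights 96, the arrays of the model 0, the arrays of the 2 groups 0, a threshold of 0.10 gave 14, the index as a covariate 17 and leaving out HFD 1 and CMPF 3 gave 3. Leaving out 1 array gave 0 (HFD 3, CMPF 2) to 6 (HFD 2). Fkbp5 was lost without each of HFD 1, HFD 3, CMPF 1, CMPF 2 and CMPF 3 (adjusted p 0.106 to 0.164), Mogat1 without HFD 3, CMPF 1, CMPF 2 or CMPF 3 (0.06 to 0.164), Cyp2c38 without HFD 2, HFD 3, CMPF 1, CMPF 2 or CMPF 3 (0.0986 to 0.261) and Nt5e without HFD 3, CMPF 1 or CMPF 2 (0.053 to 0.12). For CMPF on HFD against chow in reversal (265 genes), array weights gave 2734, the arrays of the model 59, the arrays of the 2 groups 8, a threshold of 0.10 gave 636 and leaving out HFD 1 and CMPF 3 gave 71. Leaving out 1 array gave 73 (CMPF 3) to 264 (chow 1). For genes whose CMPF effect differs (0), array weights gave 45 and leaving out reversal HFD 1 and CMPF 3 gave 1. For genes whose HFD effect differs (1453), every probe set gave 3123, array weights 2804, a threshold of 0.10 gave 2833, the index as a covariate 0, leaving out reversal HFD 1 and CMPF 3 gave 217 and leaving out prevention chow 1 and 3 gave 0. Leaving out 1 array gave 0 (prevention chow 1) to 2400 (reversal chow 1).

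Of the lists, HFD in prevention (5) had 9 with quantile normalisation, 11 with array weights, 9 with the arrays of the model, 8 with those of the 2 groups, 14 with the preset correlation, 0 with an estimated one, 2 with the index and 0 without chow 1 and 3. CMPF in prevention (0) had 1 with array medians subtracted, 3 with array weights, 13 with the preset correlation and 1 with all 18 arrays, and 0 to 2 (without HFD 3) on leaving out 1 sample. CMPF on HFD against chow in prevention (2) had 2 with the arrays of the model, neither of them the ATF4 or the pericentral list, 1 with quantile normalisation, 1 with cyclic loess, 4 with array weights, 0 with the arrays of the 2 groups, 11 with the preset correlation, 1 with an estimated one, 0 with the index and 0 without chow 1 and 3, and 0 (without CMPF 1) to 2 on leaving out 1 sample. HFD in reversal (6) had 4 with quantile normalisation, 4 with cyclic loess, 11 with 60% of probe sets dropped, 12 with array medians subtracted, 3 with the arrays of the model, 1 with those of the 2 groups, 11 with the preset correlation, 0 with an estimated one, 1 with the index and 1 without HFD 1 and CMPF 3, and 2 (without HFD 1) to 7 (without HFD 2). CMPF in reversal (0) had 2 with array medians subtracted, 7 with array weights, 15 with the preset correlation, 2 with all 18 arrays and 1 with the index, and 0 to 1 (without HFD 2). CMPF on HFD against chow in reversal (5) had 3 with the arrays of the model, 0 with an estimated correlation and 1 without HFD 1 and CMPF 3, and 2 (without CMPF 1 or CMPF 3) to 6 (without chow 3). The difference of CMPF effects (0) had 1 with array weights and 11 with the preset correlation, and 0 to 1 (without prevention HFD 2 or reversal HFD 2). The difference of HFD effects (2) had 6 with array medians subtracted, 5 with cyclic loess, 1 with array weights, 5 with the preset correlation, 0 with an estimated one, 0 with the index and 0 without prevention chow 1 and 3, and 1 to 3 (without prevention chow 2).

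The median CMPF effect in prevention over genes that HFD raised in reversal (-0.00548) was 0.00304 with no filter, with 60% dropped and without reversal HFD 1 and CMPF 3, 0.0236 with array medians subtracted, 0.0211 with the trended prior, 0.0325 with 200 genes and 0.0483 with the index, and -0.115 to 0.0417 on leaving out 1 sample. Over the genes lowered (-0.0328) it was 0.0035 with 60% dropped and 0.0026 with array medians subtracted, and -0.0682 to 0.0568. The CMPF effect in reversal over genes that HFD raised in prevention (-0.0621) passed by its p unadjusted for the 4 sets at -0.127 with array medians subtracted, -0.0621 with the preset correlation, -0.101 with 50 genes, -0.156 with the index and -0.0607 without prevention chow 1 and 3, and was -0.171 to 0.00472 on leaving out 1 array. Over the genes lowered (-0.0235) it was 0.000553 with array weights, 0.0397 with the index and 0.0208 without prevention chow 1 and 3, and -0.107 to 0.078. The correlation of HFD effects (-0.201) was 0.143 with the index, and that of CMPF effects (-0.0179) was -0.1 to 0.0854 on leaving out 1 sample.

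The numbers of the samples showed no steady pairing: over 18 pairs of arrays with the same number in 2 groups of a model, the deviations correlated at -0.368 to 0.442, over 0.1 in 6. Arrays with different numbers were not set beside them, so pairing cannot be excluded. With the number as a replicate block, the counts were 200 genes for HFD in reversal and 3 for CMPF in reversal (1 of them, Nt5e, among the 5; the calls of Mogat1, Cyp2c38 and Fkbp5 were lost, with adjusted p of 0.053, 0.053 and 0.0813), 1 list for the difference of HFD effects, and medians of 0.0155 for CMPF in prevention over genes that HFD lowered in reversal and -0.113 for CMPF in reversal over genes that HFD raised in prevention; G6pc with CMPF in prevention was 0.059 with the block.

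The gene values that reversed had not passed. For HFD in prevention, Srebf1 was 0.13 with quantile normalisation, 0.12 with cyclic loess, 0.48 with the index, 0.30 without chow 1 and 3 and -0.25 to 0.19 on leaving out 1 array. Acacb was -0.084 without chow 1 and 3. Ppara was 0.092 with the index. Scd1 was 0.37 with the mean of its probe sets, 0.0074 with quantile normalisation, 0.061 with cyclic loess, 1.32 with the index, 0.24 without chow 1 and 3 and -0.52 to 0.40 on leaving out 1 array. For CMPF in prevention, Ppara was 0.044 with the mean of its probe sets. Leaving out 1 sample gave -0.30 to 0.035 for Ppara, -0.34 to 0.13 for G6pc, -0.73 to 0.049 for Fasn and -0.33 to 0.005 for Acaca. For HFD in reversal, Acacb was 0.043 with the index and 0.22 without HFD 1 and CMPF 3 (-0.34 to 0.22 on leaving out 1 array). Scd1 was 0.33 with the mean of its probe sets (-1.01 to 0.050). Cpt1a was -0.067 with the mean of its probe sets, -0.17 with quantile normalisation, -0.14 with cyclic loess, -0.041 with the index and -0.026 without HFD 1 and CMPF 3 (-0.026 to 0.12). Ppara was -0.12 with quantile normalisation, -0.081 with cyclic loess, -0.011 with the index and -0.067 without HFD 1 and CMPF 3 (-0.067 to 0.27). For CMPF in reversal, Srebf1 was 0.027 with array weights (-0.36 to 0.30 on leaving out 1 array). Acaca was 0.0071 with cyclic loess (-0.12 to 0.057) and Cpt1a was 0.011 with quantile normalisation and 0.0055 with cyclic loess (-0.11 to 0.055). Leaving out 1 array gave -0.27 to 0.14 for Fasn and -0.51 to 0.062 for Acacb.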

Other observations

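The test of shared HFD arrays, the test of the time of day, the test of a common CMPF effect and its splits by model in this part were chosen after the results were seen. In some cell type and pathway lists that did not pass fry, most members had the same sign. The macrophage and monocyte markers had negative values in 18 of 20 genes with CMPF in prevention (median -0.477, adjusted p = 0.762), and the interferon response in 17 of 18 genes there (median -0.309, 0.803) and in 16 of 18 with CMPF in reversal (median -0.465, 0.773). In prevention 1 array, HFD 1, stood apart: without it the interferon genes were positive in 15 of 18 (median 0.193) and the macrophage markers negative in 13 of 20 (median -0.0795), with a median of -0.0614 without CMPF 1. The macrophage median in prevention was larger in size without HFD 3 (-0.816) or CMPF 2 and 3 (-0.909). In reversal the interferon median was -0.168 without HFD 1 and -0.798 without HFD 3. The genes of the mitochondrial respiratory chain were positive in 21 of 21 with HFD in reversal (median 0.257, 0.0541). The pancreatic acinar markers, which liver hardly expresses, were negative in 9 of 9 with HFD in prevention (median -0.889, 0.304) and in 8 of 9 with HFD in reversal (median -0.624, 0.599), with medians of -0.271 without prevention chow 3 and -0.125 without reversal chow 1. The stellate cell and fibrosis genes had medians of 0.345 (0.104) with HFD in prevention and 0.0482 (0.614) in reversal, and the hepatocyte core genes -0.213 (0.102) and 0.0719 (0.34).

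For the 5 genes that CMPF changed in reversal, RNA integrity is argued against, as the index differed by only 0.0094 between the group means. All 5 passed with the index as a covariate, but so small a difference cannot move the effects (Mogat1 -2.096 without and -2.095 with it). That result is therefore no further support. Without the reversal arrays of lowest index, HFD 1 and CMPF 3, only Nt5e of the 5 passed, with fewer arrays. Chance highs in the shared HFD arrays as the whole of the rise with HFD are argued against for 2 genes, Mogat1 and Cyp2c38. Both also rose with HFD in the prevention arrays (1.59 ± 0.289 and 1.64 ± 0.249). With the index they were at 1.81 ± 0.359 and 1.63 ± 0.321 there, where the larger SE ended both calls (adjusted p = 0.0715). Such highs may still have enlarged their falls with CMPF, which were smaller in prevention (-0.70 ± 0.323 and -0.47 ± 0.278). By how much cannot be told from this test. For Nt5e, chance highs cannot be told apart from an effect of CMPF, as its rise with HFD in prevention did not pass. It was 0.559 ± 0.192 there (adjusted p = 0.0954) and 0.75 ± 0.231 with the index (0.204). A different time of day at collection might raise Fkbp5 together with clock genes, but the evening genes (mean 0.444, 8 of 10 positive) and the morning genes (0.221, 3 of 5 positive) were only 0.223 apart (exact two-sided permutation p = 0.3), which lies between the values written for either outcome and cannot decide. An effect of CMPF stays open as a hypothesis, and a glucocorticoid or feeding difference between the groups was not tested.

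Of the 18 genes of the unfolded protein response, 17 had negative values with HFD (median -0.715) and 18 positive values with CMPF (median 0.726) in prevention, where the list did not pass in either comparison. For the rise with CMPF, RNA integrity as the whole cause is argued against, as the index was no lower with CMPF (2.95 against 2.84). The median was 0.719 with the index as a covariate, but so small a difference in the index cannot move it. That value is therefore no further support. For the fall with HFD, where the index differed by 1.42, the median was -0.69 with the index as a covariate. A part of RNA integrity in that fall is not excluded. The near-identical arrays are argued against too, since CMPF replicate 1 as the only CMPF sample gave a median of 0.535. Chance lows in the 3 shared HFD arrays cannot be told apart from a real fall and rise, because CMPF-treated mice on HFD differed from chow mice by a median of only -0.0795. With HFD in reversal all 18 genes were positive (median 0.482), and with CMPF in reversal 17 of 18 (0.274).

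A hypothesis found in these data is that CMPF may lower female-biased liver genes: for the mean of the CMPF effects of the models, the list had a fry adjusted p = 0.00466 (11 of 13 negative, median -0.258; adjusted p = 0.00607 with an estimated correlation), and it was the only 1 of the 40 lists to pass. Without its 4 most changed members, Cyp2b9, Cyp2b13, Hao2 and Cd36, the other 9 had a fry p of 0.0316 from the limma fit (7 negative, median -0.105), which came from prevention (8 negative, median -0.313, fry p of 0.00592 from the limma fit). In reversal these 9 were 5 negative and 4 positive (median -0.0136, fry p of 0.963), so that there the 4 could be the whole of the fall. Both CMPF effects are taken against the HFD arrays in which this list was called upward. Set against chow in reversal, the 4 did not pass: Hao2 at -0.0051, Cyp2b13 at -0.14, Cyp2b9 at 1.95 and Cd36 at 0.78. How far chance highs in the HFD arrays make up the fall cannot be told. The list already had the smallest adjusted p by fry with CMPF in each model (0.0884 and 0.0591), so the later test of the mean is no independent support. The male-biased genes had the opposite sign to this list, positive in 15 of 16 (median 0.419, adjusted p = 0.118). By limma 0 genes passed for the mean effect (688 at an unadjusted p under 0.05), with Nt5e (-0.93 ± 0.144) and Mogat1 (-1.40 ± 0.216) lowest at an adjusted p of 0.0976.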
